A study of Mus musculus with 12 samples.

How the data were processed

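The data are RNA-seq gene counts of mouse T-ALL cells from 3 untreated mice and 3 mice given doxycycline for 3 days, with 2 sequencing runs of each RNA. Per the labels' protocols, cells were isolated from leukemic spleens by flow sorting, RNA was prepared with the QIAGEN RNeasy plus mini kit, and libraries followed standard Illumina protocols. The labels give 1 batch date for all 12 libraries. The authors deposited raw counts per gene under Entrez gene identifiers, with a gene length, in 1 table per library and in a whole-series table. Per the submitters' processing notes, CASAVA 1.8.1 and featureCounts were used with the mm10 build. The aligner, the gene annotation, the treatment of reads with several matches and the strand setting are not given in the sources used here. Genes that overlap, have antisense partners or have near-identical copies can therefore share or lose reads. The counts in the whole-series table equalled those of the per-library tables for all 27179 genes in 12 of 12 libraries, so the per-library tables were used.

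Symbols came from a RefSeq table of GRCm38, matched on the Entrez identifier, and for the mitochondrial genes and missing identifiers from GENCODE metadata. Of 27179 identifiers, 25293 (93.1%) received a symbol. All identifiers stayed in the library totals and tests. Identifiers without a symbol took between 0.663% and 1.84% of the counts per mouse.

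Counts of the 2 runs were summed per mouse, so n is the number of mice. Totals were 29904744 to 44949303 counts per mouse, at which 1 CPM corresponds to 29.9 to 44.9 counts, and a count of 0 allows up to 0.0667 to 0.10 CPM (3 counts). Groups were compared with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, robust dispersions, and the quasi-likelihood F test with no block, with Benjamini-Hochberg adjustment at 0.05. The filter kept 13134 genes. SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. No exact permutation test of 3 against 3 mice can give a p below 0.1.

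In all, 33 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. Adjustment was over the 33 lists. At the preset correlation 11 lists passed, and with an estimated correlation 0 did. With it, 2 lists had an unadjusted camera p under 0.05 (T-cell receptor complex and cytokine signalling), and fry passed 14 lists. Of the listed genes, Hbb-b2, Hbb-bt and Ahsp had no match, and 2 listed symbols were older names of another listed gene. The test fry was used for the direction of a list, and it does not compare a list with other genes.

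The groups, tests, gene lists, alternatives and naming rule were fixed before the data were examined, except where the text says otherwise. Named genes were the Ikaros family, the 15 largest rises and 15 largest falls, up to 4 members with the smallest p per list, and the 5 genes with the smallest p. The largest changes had to have an adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between groups and an official symbol that is not a placeholder. Other genes named in the report (Cd3g, Gapdh, Gzma, Hbb-b1, Il7r, Lyz2, Mki67, Notch1 and Notch3) were chosen after their values were seen. Some genes that the rule takes are not reported here.

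The tests were checked on simulated counts for 3 against 3 mice, drawn with the real means, library sizes and dispersions. In each of 5 simulated tables of 13134 genes, 200 genes were changed. edgeR recovered 49.9% of genes changed 1.5-fold, 70.1% at 2-fold and 93.0% at 4-fold, and 8.87% of its calls were false. DESeq2 recovered 59.4%, 73.1% and 90.9% with 20.6% false calls, and limma-voom 44.5%, 64.5% and 92.1% with 8.48%. A simulated list of 20 genes raised 1.5-fold had a camera p of 9.3e-30, and an unchanged list of 20 genes had 0.862. In the real comparison 6571 genes passed, far more than the 200 changed per simulated table, so these shares do not carry over to it. Simulated genes were drawn independently, so the list check holds no correlation between genes. The estimated correlation of the real Myc target and ribosome biogenesis list was 0.603.

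Alternatives were other size factors (RLE, upper quartile, library totals only), no filter or a filter of over 1 CPM in 3 mice, DESeq2 1.42.0, limma-voom with and without quality weights, a fit that is not robust, each run alone, the replicate number as a block, and leaving out each mouse in turn. A fit without both untreated mouse 3 and doxycycline mouse 2 was added after seeing the data. No columns or libraries were left out of the main comparison.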

Results

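RNA-seq was performed on T-cell acute lymphoblastic leukemia (T-ALL) cells of a single mouse primary leukemia, ALL101. In this model a tetracycline-off transactivator drives a GFP-linked short hairpin RNA against Ikaros, a zinc-finger transcription factor of lymphocytes encoded by Ikzf1. Recipient mice bearing the leukemia were left untreated (3 mice) or received doxycycline for 3 days (3 mice), which per the labels shuts off the hairpin and restores endogenous Ikaros. Per the labels, leukemia cells were sorted from spleen, and each RNA was sequenced in 2 runs, which gave 12 libraries. The library name of untreated mouse 3 carries INJ in place of the GFP-sort wording of the other mice. Whether that mouse was sorted alike is not known here. The comparison asks how the transcriptome of established leukemia cells changes once Ikaros is restored. Summed over the 2 runs, the untreated mice had 30133066, 33063390 and 29904744 counts and the doxycycline mice 33899095, 44949303 and 43771797. The labels give the sorted cells as GFPhigh in all untreated mice and GFPmid in all doxycycline mice, so the treatment and the gate cannot be separated. None of the 12 libraries is of a leukemia without the hairpin given doxycycline. Changes after doxycycline therefore cannot be divided between restored Ikaros and doxycycline itself. Values are CPM (counts scaled by TMM to a common library size) as mean ± SD of 3 mice, and log2 fold changes are doxycycline minus untreated ± SE.

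Ikzf1, the gene targeted by the hairpin, was 9.66-fold higher after doxycycline. Its level went from 154 ± 4.54 to 1486 ± 43.4 CPM (n = 3 each), a log2 fold change of 3.27 ± 0.07 (edgeR adjusted p = 1.2e-07). Each untreated mouse lay between 150 and 159 CPM and each doxycycline mouse between 1438 and 1523 CPM, in the direction of the labels. Ikzf1 (Entrez ID 22778) is a protein-coding gene on chromosome 11 at 11684962 to 11772930 of GRCm38 (mm10). It also had the smallest p of all tested genes. Of the related family members, Ikzf3, encoding Aiolos, rose by 0.37 ± 0.07 log2 units (edgeR adjusted p = 0.0023). Ikzf2, encoding Helios, had a log2 difference of 0.96 ± 0.36 that did not pass the threshold (edgeR adjusted p = 0.080). Doxycycline mouse 2 held 129.7 CPM of Ikzf2, against 331 and 285 CPM in doxycycline mice 1 and 3. Ikzf4 and Ikzf5 had log2 differences of 0.13 ± 0.21 and -0.02 ± 0.07 (edgeR adjusted p = 0.631 and 0.819). Of the family of 5, 2 members rose and 0 fell. The number that rose was 3 with DESeq2, with limma-voom and quality weights, with a fit that is not robust, and without doxycycline mouse 2. The list did not pass (camera adjusted p = 0.076) unless doxycycline mouse 2 was left out (0.028). With all mice, its adjusted p = 0.627 with an estimated correlation.

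**Figure D1:**
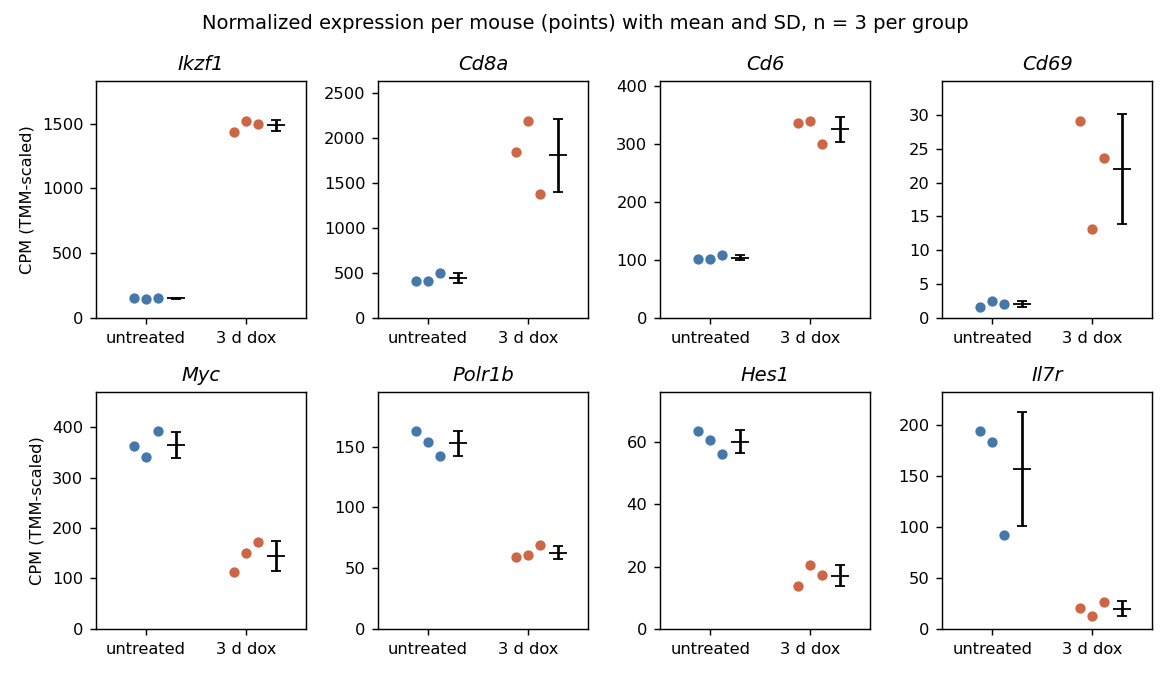
Normalized expression (CPM, TMM-scaled, linear axes from 0) of 8 genes in the 3 untreated and 3 doxycycline mice. Points are mice, and the bars beside them are the mean and SD. Ikzf1 lay at 154 ± 4.54 CPM in untreated and 1486 ± 43.4 CPM in doxycycline mice, and no gene shown had overlapping groups.

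Prf1, Cd69 and Cd44 were among the largest rises, and Dlk1 and Kit among the largest falls. Prf1, encoding the pore-forming protein perforin, rose 17.9-fold from 0.405 ± 0.244 to 7.23 ± 1.04 CPM. Cd69, an early activation antigen that restrains egress, rose 10.4-fold from 2.10 ± 0.429 to 22 ± 8.09 CPM, and Cd44, a hyaluronan receptor, rose 8.86-fold from 4.06 ± 0.817 to 36.0 ± 12 CPM. Dlk1, a Notch-related transmembrane ligand, fell from 7.12 ± 4.97 to 0.0553 ± 0.0327 CPM, near the level that a count of 0 allows, and Kit, the stem cell factor receptor of early progenitors, fell 21.6-fold from 36.0 ± 17.6 to 1.65 ± 0.699 CPM. Il9r, encoding the interleukin-9 receptor, fell 3.98-fold from 230.1 ± 7.77 to 57.8 ± 3.30 CPM. Their edgeR adjusted p-values were 0.00011 for Prf1, 0.00037 for Cd69, 0.00037 for Cd44, 0.0025 for Dlk1, 0.0022 for Kit and 5.0e-06 for Il9r. The 15 largest rises ran from Arap2 (log2 fold change 4.76 ± 0.89) through Cfap74, Prf1, Tgfb3, Gpr174, Ampd1, Cntnap1, Gng2, Cd69, Pacsin1, Zfp831, Ikzf1, Crybg1 and Cd44 to Abcb1a (3.13 ± 0.49). The 15 largest falls were Dlk1, Ccn4, Faxc, Necab1, Bmp1, Obsl1, Lhfpl2, Zfp518b, Fbp1, Bex1, Kit, Rbpms, Vash2, Trgc2 and Scn4b, from 6.88 ± 1.01 log2 units for Dlk1 to 4.11 ± 0.60 for Scn4b. Trgc2 is a T-cell receptor gamma constant gene with near-identical copies, so its level is uncertain. After Ikzf1, Il9r, Tns3 and Maged1 were among the genes with the smallest p-values, and fell by 1.99 ± 0.07, 2.34 ± 0.10 and 2.65 ± 0.11 log2 units. Without untreated mouse 2, the edgeR adjusted p was 0.0504 for Arap2, 0.0611 for Gng2 and 0.0545 for Faxc, and without doxycycline mouse 2 it was 0.0641 for Faxc. With the replicate number as a block it was 0.0718 for Faxc and 0.0505 for Rbpms. Without both untreated mouse 3 and doxycycline mouse 2, a setting added after the data were seen, it was 0.0761 for Arap2 and 0.138 for Bex1. Arap2 was at 52.8, 13.7 and 12.5 CPM in the doxycycline mice, and without doxycycline mouse 1 its log2 fold change was 3.76, below that of Cfap74 (4.19). Without untreated mouse 3 the log2 fold change was 5.46 for Arap2, 4.61 for Tgfb3, 4.39 for Cntnap1, 4.33 for Gng2 and 3.88 for Abcb1a. It was -4.07 for Faxc and -3.76 for Bex1 without untreated mouse 2, -4.56 for Faxc without doxycycline mouse 2 and -6.09 for Ccn4 without untreated mouse 1. Without doxycycline mouse 3 it was -5.74 for Necab1, -5.38 for Rbpms and -5.0 for Trgc2.

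Of 13134 genes tested, 3255 were higher and 3316 lower after doxycycline in edgeR's quasi-likelihood test at an adjusted p under 0.05. These 6571 genes made up 50.0% of the genes tested. A change of at least 2-fold was found for 1851 of them, 1080 higher and 771 lower. The 3 values of each group did not overlap for 8036 genes (61.2%), where chance gives 10%. The biological coefficient of variation was 13.9%. The median log2 fold change over all tested genes was -0.0037. Levels are scaled to a common library size, so this median is largely set by the scaling. A common shift of all genes would not show in it.

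Genes of ribosome biogenesis fell together. Of the list of Myc targets and ribosome biogenesis genes, 24 of 24 tested members were lower and 0 higher (camera adjusted p = 9.1e-10, and adjusted p = 0.627 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, fell by 1.28 ± 0.08 log2 units from 153 ± 10.3 to 62.8 ± 5.22 CPM (edgeR adjusted p = 3.9e-05). Utp20, Wdr12 and Mybbp1a fell by 0.81, 0.81 and 0.86 log2 units. Myc itself, placed in the Notch list below, fell by 1.33 ± 0.15 log2 units (edgeR adjusted p = 0.00044). In the list of DNA replication and G1/S genes, 14 of 26 members fell and 1 rose (camera adjusted p = 0.0088, and adjusted p = 0.744 with an estimated correlation), and adjusted over the list alone 15 fell and 1 rose. Without doxycycline mouse 2, 3 members rose. Tyms, encoding thymidylate synthase, fell by 0.49 ± 0.07 log2 units, and Mcm6, a replicative helicase subunit, by 0.51 ± 0.09, whereas the transcription factor gene E2f2 rose by 0.65 ± 0.08 (edgeR adjusted p = 0.00098, 0.0022 and 0.00043). In the G2/M and mitosis list, 3 of 26 members fell and 1 rose (camera adjusted p = 0.396), and adjusted over the list alone 3 fell and 0 rose. Without doxycycline mouse 3, 6 members fell and 0 rose, and the number that rose was 0 without untreated mouse 1 or 2 and 2 without doxycycline mouse 1. Mki67, a proliferation marker, was at 1828 ± 68.3 CPM in untreated and 1990.0 ± 94.4 CPM in doxycycline mice, which did not pass (edgeR adjusted p = 0.166).

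Transcripts of the mitochondrial genome and of nuclear respiratory-chain genes moved in opposite directions. All 13 mitochondrially encoded genes rose, with a median log2 fold change of 0.64 (camera adjusted p = 2.6e-05, and adjusted p = 0.627 with an estimated correlation). mt-Cytb, encoding cytochrome b, rose by 0.72 ± 0.08 log2 units from 2532 ± 201 to 4176 ± 74.1 CPM (edgeR adjusted p = 0.00022). Without strand information in the sources used here, mt-Nd6, which lies on the other strand from its neighbours, cannot be separated from antisense reads. Of 21 nuclear-encoded oxidative phosphorylation genes, 16 fell and 0 rose (camera adjusted p = 0.00083, and adjusted p = 0.657 with an estimated correlation), and adjusted over the list alone 18 fell. The falls were small, with a median of -0.24, and Atp5b, encoding the ATP synthase beta subunit, fell by 0.38 ± 0.08 log2 units (edgeR adjusted p = 0.0047). The number of lower members was 8 without untreated mouse 1, 7 without untreated mouse 2 and 10 without doxycycline mouse 1. In the glycolysis list, 9 of 19 members fell and 2 rose (camera adjusted p = 0.282), and only 1 rose without untreated mouse 1 or 2 or without doxycycline mouse 1 or 3. Pfkl, a phosphofructokinase gene, fell by 0.86 ± 0.11 log2 units, and Slc2a1, a glucose transporter gene, rose by 0.64 ± 0.15 (edgeR adjusted p = 0.00046 and 0.0085). Of 20 integrated stress response genes, 10 fell and 2 rose (camera adjusted p = 0.016, and adjusted p = 0.744 with an estimated correlation), and adjusted over the list alone 11 fell and 2 rose. Without any 1 mouse other than doxycycline mouse 2, the number that rose was 1. Slc7a5, an amino acid transporter gene, fell by 1.00 ± 0.13 log2 units, and Phgdh, the first enzyme of serine synthesis, by 0.80 ± 0.11 (edgeR adjusted p = 0.00065 and 0.00071). In the cholesterol synthesis list 3 of 19 members rose and 0 fell, while adjusted over the list alone 0 did either (camera adjusted p = 0.817). Without untreated mouse 1 the number that rose was 0, without doxycycline mouse 1 it was 1, and without doxycycline mouse 2, 6 rose and 1 fell.

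Genes of the T-cell receptor complex and its signalling were mostly higher after doxycycline. Of 22 members, 17 rose and 1 fell (camera adjusted p = 1.3e-05, and adjusted p = 0.627 with an estimated correlation). Cd6, a scavenger-receptor family regulator of receptor signalling, rose by 1.64 ± 0.07 log2 units (edgeR adjusted p = 1.6e-05). The costimulatory receptor gene Cd27 rose from 172 ± 5.39 to 373 ± 27.7 CPM, and Prkcq, encoding protein kinase C theta, from 134 ± 7.48 to 288 ± 19.4 CPM (edgeR adjusted p = 3.9e-05 and 4.7e-05). Cd3g fell by 0.45 ± 0.07 log2 units (edgeR adjusted p = 0.00094). In the pre-TCR and immature thymocyte list 8 of 19 members rose and 4 fell (camera adjusted p = 0.467), and adjusted over the list alone 8 rose and 5 fell. The coreceptor gene Cd8a rose from 446 ± 52.2 to 1809.6 ± 407 CPM, Cd1d1 rose by 1.14 ± 0.13 log2 units, and Dntt, encoding terminal transferase, fell by 1.59 ± 0.16 (edgeR adjusted p = 0.00024, 0.00036 and 0.00030). In the T-cell maturation and egress list 12 of 20 members rose and 4 fell (camera adjusted p = 0.010, and adjusted p = 0.629 with an estimated correlation). Foxo1, a transcription factor gene of quiescent T cells, rose by 2.01 ± 0.15 log2 units, Ifngr1 by 1.11 ± 0.09 and Slfn1 by 2.80 ± 0.21 (edgeR adjusted p = 9.0e-05, 7.8e-05 and 6.9e-05). Il7r, encoding the interleukin-7 receptor alpha chain, fell by 2.97 ± 0.42 log2 units (edgeR adjusted p = 0.0035). Of 20 adhesion and chemokine receptor genes, 12 rose and 4 fell (camera adjusted p = 0.056), and the list passed without untreated mouse 1 (0.048) or doxycycline mouse 2 (0.032). With all mice, the adhesion list had an adjusted p = 0.744 with an estimated correlation. Itgal and Itgb2, which encode the chains of the integrin LFA-1, rose by 1.17 ± 0.11 and 0.97 ± 0.10 log2 units, and Itgb1 fell by 0.95 ± 0.08 (edgeR adjusted p = 0.00015, 0.00017 and 9.0e-05).

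In the Notch list, 8 of 17 members fell and 2 rose (camera adjusted p = 0.069). Hes1, a direct Notch target, fell from 60.2 ± 3.76 to 17.1 ± 3.39 CPM, and Igf1r from 90.3 ± 2.12 to 23 ± 5.67 CPM (edgeR adjusted p = 8.7e-05 and 0.00012). Runx1 fell by 0.70 ± 0.06 log2 units (edgeR adjusted p = 0.00012). Doxycycline mouse 2 stood apart from the other treated mice in several members. Notch1 was at 1298 CPM in that mouse against 575 and 695 CPM in doxycycline mice 1 and 3, and Notch3 at 574 CPM against 154 and 162 CPM. Without doxycycline mouse 2, 11 members fell and 3 rose, and the list passed (camera adjusted p = 0.0086). It also passed without untreated mouse 1 (camera adjusted p = 0.045), and with all mice had an adjusted p = 0.744 with an estimated correlation.

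Tested genes of the cytokine signalling and SOCS list were also mostly higher, whereas the receptor genes Il9r and Il7r, outside that list, fell as given above. Of 21 members of the cytokine signalling and SOCS list, 15 rose and 1 fell (camera adjusted p = 0.00022, and adjusted p = 0.627 with an estimated correlation). The number that fell was 0 without doxycycline mouse 1 or 2 and 2 without doxycycline mouse 3. Jak2 rose by 1.16 ± 0.09 log2 units, Il21r by 1.16 ± 0.10 and Il4ra by 2.45 ± 0.22 (edgeR adjusted p = 6.9e-05, 9.9e-05 and 0.00027). Of 13 cell-cycle inhibitor genes, 9 rose and 2 fell (camera adjusted p = 0.043, and adjusted p = 0.627 with an estimated correlation). The camera adjusted p was 0.055 without untreated mouse 2 and 0.070 without doxycycline mouse 3. Rbl2, encoding the retinoblastoma-like protein p130, rose by 1.22 ± 0.09 log2 units and Cdkn2d by 1.24 ± 0.13, whereas Cdkn1a, encoding p21, fell by 3.72 ± 0.29 (edgeR adjusted p = 5.2e-05, 0.00025 and 0.00018). Among 18 p53 targets, 6 rose and 6 fell (camera adjusted p = 0.659), and adjusted over the list alone 7 rose and 6 fell. Gadd45a and the death receptor gene Fas rose by 1.90 ± 0.13 and 2.13 ± 0.20 log2 units (edgeR adjusted p = 3.9e-05 and 0.00020). In the BCL2 family list 6 of 14 members rose and 3 fell (camera adjusted p = 0.396), and adjusted over the list alone 7 rose and 3 fell. Bcl2l11, encoding the pro-apoptotic protein BIM, rose by 0.81 ± 0.14 log2 units, the anti-apoptotic gene Mcl1 rose by 0.55 ± 0.09, and Bid fell by 0.59 ± 0.07 (edgeR adjusted p = 0.0023, 0.0016 and 0.00044). Of 17 immediate early and heat shock genes, 8 rose and 3 fell (camera adjusted p = 0.056). Egr1, Nr4a1 and Dusp2, which are induced by antigen receptor signals, rose by 2.66 ± 0.21, 2.30 ± 0.20 and 1.48 ± 0.07 log2 units (edgeR adjusted p = 0.00023, 0.00030 and 2.0e-05). Without untreated mouse 1, untreated mouse 3 or doxycycline mouse 1 this list passed, with camera adjusted p-values of 0.045, 0.042 and 0.032, and with all mice it had an adjusted p = 0.627 with an estimated correlation. Of 24 interferon-stimulated genes, 13 rose and 5 fell (camera adjusted p = 0.078), and adjusted over the list alone 15 rose and 5 fell. Without doxycycline mouse 2, 3 fell and the list passed (camera adjusted p = 0.028), and with all mice it had an adjusted p = 0.755 with an estimated correlation. Zbp1 rose by 2.54 ± 0.17 log2 units and Bst2 fell by 1.66 ± 0.12 (edgeR adjusted p = 6.7e-05 and 6.6e-05).

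In the remaining lists of leukemia cell genes, members moved both ways. In the NuRD and Ikaros corepressor list 4 of 17 members rose and 4 fell (camera adjusted p = 0.688), with a median log2 fold change of -0.02 and a mean of 0.07. Chd3, encoding a NuRD helicase, rose by 0.89 ± 0.10 log2 units (edgeR adjusted p = 0.00027). The number that fell was 1 without untreated mouse 2 or without doxycycline mouse 2, and 2 without untreated mouse 1 or doxycycline mouse 1. Of 16 antigen presentation genes 6 rose and 3 fell (camera adjusted p = 0.505). Nlrc5, a transactivator of class I genes, rose by 2.06 ± 0.26 log2 units and the class II gene H2-Aa fell by 2.98 ± 0.40 (edgeR adjusted p = 0.00081 and 0.0011). Only 6 of 20 T-ALL oncogenes and progenitor genes had enough counts to be tested, of which Fli1 rose by 0.47 ± 0.10 log2 units and Kit fell (edgeR adjusted p = 0.0055 for Fli1). That list had a median of 0.46 and a mean of -0.31 (camera adjusted p = 0.490), and the number that rose was 3 without untreated mouse 1 and 2 without doxycycline mouse 2 or 3. In the housekeeping list 2 of 15 members rose and 7 fell (camera adjusted p = 0.248), and adjusted over the list alone 2 rose and 9 fell. Actb rose by 0.53 ± 0.07 log2 units and Eef1a1 fell by 0.42 ± 0.08 (edgeR adjusted p = 0.00062 and 0.0027). The number of housekeeping genes that fell was 3 without untreated mouse 2 and 4 without untreated mouse 1 or doxycycline mouse 1. Gapdh was counted at only 5.60 ± 0.733 CPM in untreated mice, and it has near-identical copies elsewhere in the genome, so its level is uncertain. For the 23 lists with no separate count given, adjustment over the list alone left the counts as they were.

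**Figure D2:**
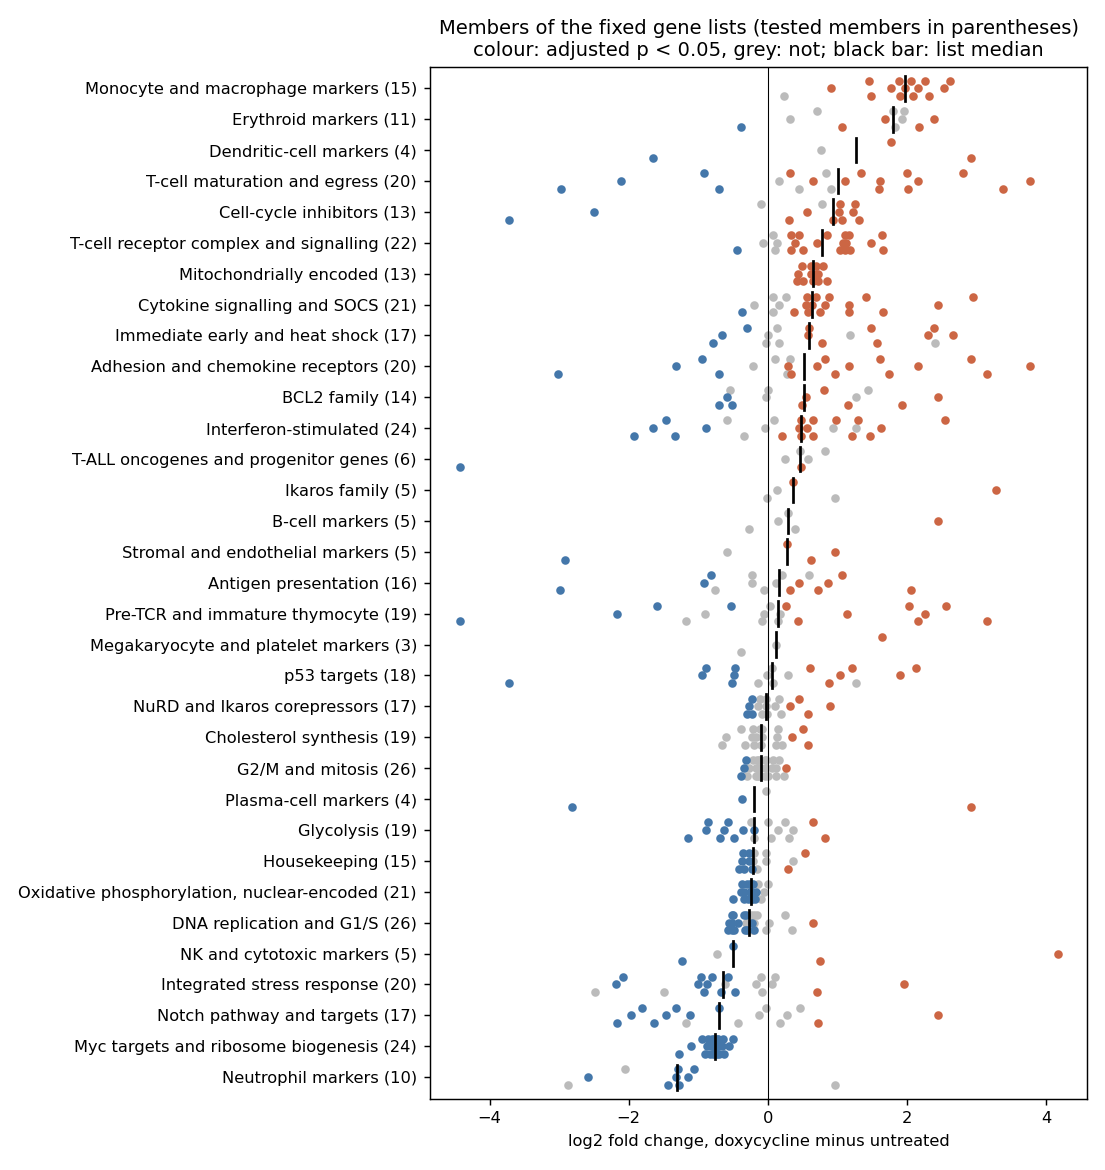
Log2 fold change (doxycycline minus untreated, x axis) of each tested member of the 33 fixed lists, ordered by list median (black bar). Coloured points passed edgeR's test at an adjusted p under 0.05 and grey points did not. All 24 points of the Myc target and ribosome biogenesis list lie below 0, and all 13 of the mitochondrially encoded list above 0.

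Some markers of other spleen cell types moved with treatment. Of 15 monocyte and macrophage markers, 14 rose and 0 fell (camera adjusted p = 1.1e-05, and adjusted p = 0.627 with an estimated correlation). Itgam, an integrin gene of myeloid cells, went from 9.86 ± 0.820 to 44.1 ± 5.52 CPM, Hmox1, encoding heme oxygenase 1, from 7.46 ± 0.346 to 20.4 ± 4.19 CPM, and the complement gene C1qa from 1.61 ± 0.392 to 6.86 ± 2.66 CPM (edgeR adjusted p = 2.1e-05, 0.00024 and 0.0011). Lyz2, an abundant transcript of myeloid cells, was at 2.91 ± 0.715 CPM in untreated and 3.41 ± 0.282 CPM in doxycycline mice (edgeR adjusted p = 0.429). Of 10 neutrophil markers, 7 fell and 0 rose (camera adjusted p = 0.056). S100a8 fell from 3.68 ± 1.31 to 1.48 ± 0.286 CPM (edgeR adjusted p = 0.0066). The number that fell was 1 without untreated mouse 2, 3 without doxycycline mouse 1 and 2 without doxycycline mouse 3. The neutrophil list passed without untreated mouse 1, untreated mouse 3 or doxycycline mouse 2 (camera adjusted p = 0.045, 0.014 and 0.028), and with all mice had an adjusted p = 0.744 with an estimated correlation. Of 11 erythroid markers, 4 rose and 1 fell (camera adjusted p = 0.026, and adjusted p = 0.744 with an estimated correlation). Slc4a1, the anion exchanger gene of red cells, rose from 4.53 ± 3.20 to 23.6 ± 7.92 CPM (edgeR adjusted p = 0.017), and without untreated mouse 1 its edgeR adjusted p was 0.0589. Its log2 fold change was 2.39 ± 0.55, and 3.12 without untreated mouse 3. The globin gene Hbb-b1 was at 3.62, 2.02 and 16.2 CPM in the untreated mice and 30.1, 24.2 and 22.9 CPM in the doxycycline mice (edgeR adjusted p = 0.111). Globin genes have near-identical copies and are uncertain. Without untreated mouse 3, 9 erythroid markers rose, without untreated mouse 1 only 1 did, and without untreated mouse 2 or doxycycline mouse 1 the number was 2. The number that fell was 0 without untreated mouse 1 or 2 or doxycycline mouse 2 or 3. On all 6 mice, 8 erythroid markers rose with limma-voom, 9 with limma-voom and quality weights, and 7 with an edgeR fit that is not robust.

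Few markers of the other cell types had enough counts to be tested. Of 5 B-cell markers 1 rose (camera adjusted p = 0.505), namely Cd22, from 0.184 ± 0.0719 to 1.01 ± 0.683 CPM (edgeR adjusted p = 0.010). Its log2 fold change was 2.45 ± 0.60, and 1.76 without doxycycline mouse 3. Of 4 plasma-cell markers 1 rose and 2 fell (camera adjusted p = 0.659), and Prdm1 went from 0.336 ± 0.200 to 2.54 ± 0.867 CPM (edgeR adjusted p = 0.00094). Of 4 dendritic-cell markers 2 rose and 1 fell (camera adjusted p = 0.427), and these were Flt3, Ccr9 and Bst2. Ccr9, a chemokine receptor gene that thymocytes also use, rose from 91.2 ± 27.5 to 686 ± 209 CPM (edgeR adjusted p = 0.0018). Of 5 NK and cytotoxic markers 2 rose and 2 fell (camera adjusted p = 0.942), with a median of -0.51 and a mean of 0.49. The number that fell was 0 without untreated mouse 1 or doxycycline mouse 2, and 1 without any other mouse. Gzma, a granzyme gene, was at 1153 ± 309 CPM in untreated and 694 ± 323 CPM in doxycycline mice (edgeR adjusted p = 0.228). Of 3 megakaryocyte and platelet markers 1 rose (camera adjusted p = 0.659), namely the integrin gene Itgb3, from 8.41 ± 2.58 to 26.1 ± 9.11 CPM (edgeR adjusted p = 0.011). Of 5 stromal and endothelial markers 3 rose and 1 fell (camera adjusted p = 0.566), with a median of 0.27 and a mean of -0.33. Pdgfrb, a growth factor receptor gene, fell from 136 ± 30.3 to 17.9 ± 5.32 CPM (edgeR adjusted p = 0.00050).

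Mice within a group differed far more than the 2 runs of one RNA did. Across genes, the chi-square statistic of the 2 runs divided by its degrees of freedom was 1.01 to 1.03 in the 6 mice, with p from 0.0146 to 0.281. Between different mice of one group it was 5.46 to 39.4. The 2 runs of each RNA thus differed by little more than sampling noise and were counted as 1 sample. On the first principal component, which held 77.6% of the variance, untreated mice scored -55.6, -55.8 and -33.3 and doxycycline mice 51.3, 53.6 and 39.7. Untreated mouse 3 lay nearest to the doxycycline mice, and its library name lacks the GFP-sort wording that the other 5 mice carry. Without it, 3119 genes were higher and 3162 lower.

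**Figure D3:**
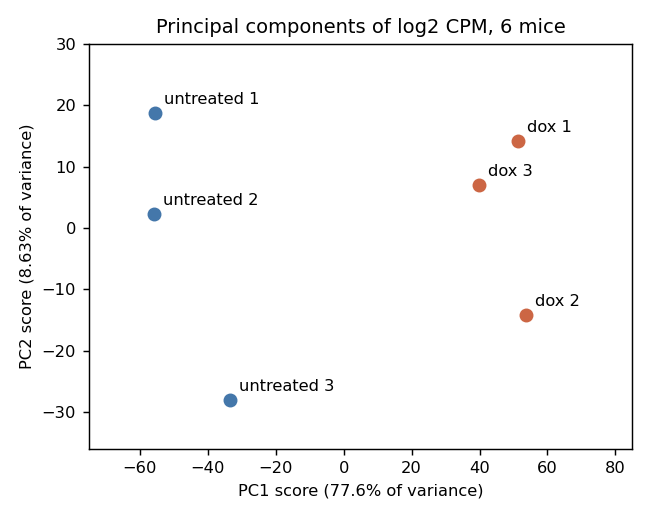
Scores of the 6 mice on the first principal components of log2 CPM (PC1 on the x axis with 77.6% and PC2 on the y axis with 8.63% of the variance). The untreated mice have negative and the doxycycline mice positive PC1 scores, with untreated mouse 3 at -33.3.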

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

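The fit without both untreated mouse 3 and doxycycline mouse 2 was chosen only after the data were seen, and all other settings were planned. Across the planned settings that kept all 6 mice, 2980 to 3721 genes were higher and 2867 to 3754 lower, and 1412 to 2117 changed at least 2-fold. Leaving out 1 mouse gave 2417 to 3136 higher, 2452 to 3162 lower and 1639 to 2087 changed at least 2-fold. Leaving out both mice gave 3281 higher and 3257 lower, of which 5775 genes were shared with the 6571 genes of the comparison of all mice. Ikzf1 stayed past the threshold in all 19 alternatives, with log2 fold changes of 3.25 to 3.30 and a largest adjusted p of 3.8e-05. Of 33 gene lists, 11 passed with a preset correlation, 0 with an estimated correlation, 14 with fry and 10 to 16 with 1 mouse left out. In the alternative, the correlation between genes of a list is estimated from the data instead of preset. The immediate early and heat shock list had an estimated correlation of -0.0214, below the preset 0.01. The unadjusted camera p of that list still went from 0.0203 to 0.0668. The p of the Ikaros family list, with an estimate of -0.0872, rose as well. Higher correlation between genes therefore cannot alone account for the larger p-values, and what else contributed was not tested. The count of 0 lists passing with an estimated correlation thus cannot be read as an effect of gene correlation alone. Other settings also moved counts within lists: 5 G2/M genes fell with DESeq2 or the block, 5 antigen presentation genes fell and 4 glycolysis genes rose with quality weights, 2 NuRD genes fell with either run alone, and 2 to 3 T-ALL oncogenes rose in several settings. With fry, the adjusted p was 0.103 for DNA replication, 0.051 for the integrated stress response and 0.059 for erythroid markers. Leaving out 1 mouse turned the direction of 2 lists and 5 genes. The cholesterol synthesis list turned without doxycycline mouse 2, with an adjusted p of 0.147 to 0.951 over the mice left out, and the NK list without untreated mouse 3, with 0.787 to 0.998, and also with fry (0.362). The log2 fold changes over the mice left out were -0.050 to 0.017 for Ikzf5 and -0.070 to 0.051 for Xbp1 (both turned without doxycycline mouse 3), -0.41 to 0.017 for Vpreb1 (doxycycline mouse 3), -0.083 to 0.52 for Cd79b (untreated mouse 1 or doxycycline mouse 2) and -0.063 to 0.25 for Itga2b (untreated mouse 1 or doxycycline mouse 3). Ikzf4 turned with run 1 only (-0.065), Ikzf5 with run 2 only (0.012) and Itga2b with limma-voom and quality weights (-0.013). None of these genes or lists passed in the comparison of all mice, and the cause was not tested. Of 159 named genes, 13 lost their call without untreated mouse 2, 11 without untreated mouse 1, 8 without doxycycline mouse 1 and 7 without doxycycline mouse 3. With the replicate number as a block, 3103 genes were higher, 3156 lower and 1806 changed at least 2-fold, and 6061 genes were shared. Under the block Faxc (0.0718) and Rbpms (0.0505) lost their call and 13 lists passed, with the neutrophil (0.0046) and adhesion (0.031) lists added. Deviations of mice with the same number correlated at 0.156, -0.012 and -0.103 across genes, and not every mouse correlated best with its own number. Centring within groups of 3 ties these values together, so they cannot decide whether the numbers pair mice. The whole-series table gave equal counts and so no separate values. Depth limited genes near the floor of 0.0667 to 0.10 CPM.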

Other observations

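The gene families grouped by symbol stem, the T-cell receptor loci and every test on untreated mouse 3 and on the macrophage markers were chosen only after the result was seen. Segments of the T-cell receptor alpha locus rose together after doxycycline. Trac, the alpha constant gene, rose from 136 ± 22.9 to 560.3 ± 6.67 CPM, a log2 fold change of 2.04 ± 0.11 (edgeR adjusted p = 2.1e-05). Of the joining segments (Traj) 26 of 27 rose and 0 fell, with a median log2 fold change of 3.09, and of the variable segments (Trav) 17 of 18 rose and 0 fell, with a median of 2.15. Traj42 held 52.4% of the tested Traj counts in untreated and 44.5% in doxycycline mice. Of the gamma locus, 2 of 3 Trgc, 2 of 2 Trgv and 2 of 2 Trgj genes fell. Most of these segments lay at low levels and share reads with similar segments, so single values are uncertain.

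The Gimap genes, which encode small GTPases of lymphocyte survival, rose in 8 of 8 tested members, with a median log2 fold change of 1.85. Of the Mrpl genes, which encode proteins of the mitochondrial ribosome, 32 of 48 fell. By symbol alone, 38 of 62 Rpl, 33 of 54 Rps and 34 of 54 Eif genes were lower. These stems also take in other genes: Rpl and Rps hold pseudogenes, Eif holds the Eif2ak kinases, and Rps holds the S6 kinase genes, among them all 3 Rps genes that rose (Rps6ka5, Rps6ka1 and Rps6kb2). Eif4ebp1, encoding a binding protein of the cap-binding factor, fell by 1.79 ± 0.12 log2 units (edgeR adjusted p = 4.7e-05). Of 201 symbol families, 24 passed camera with a preset correlation, among them Traj, Trav, Gimap, Rpl, Rps, Mrpl and Eif, and 0 passed with an estimated correlation (adjusted p = 0.672 for each of these 7 families with an estimated correlation). Ribosomal protein genes have near-identical copies, so their levels are uncertain.

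The count of 6571 changed genes was set against other splits of the 6 mice. Of the 10 splits, 1 gave as many, the real split itself, and the highest other split gave 0. Every other split mixes treated and untreated mice in both groups, so a treatment effect widens the spread within groups. Those counts of 0 therefore do not show what chance alone would give. With 10 splits, a share under 0.05 cannot be reached. Gene length was argued against as the source: with an offset per mouse that removes the trend with length, 6501 genes passed, of which 6192 were shared. Across genes, fold change and length correlated at a Spearman rho of 0.0626.

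Untreated mouse 3 lay nearer to the doxycycline mice than the other untreated mice. Its library name lacks the GFP-sort wording of the other mice, and a difference in sorting was not tested and stays open. A mixture with cells of the doxycycline profile would shift Ikzf1 and other genes by the same share of the way to the doxycycline level. Ikzf1 in that mouse was shifted by 0.548% (-0.088% and -0.462% in untreated mice 1 and 2). The median shift was 35.0% for genes that fell at least 2-fold (quartiles 13.1% to 59.3%) and 9.49% for genes that rose (quartiles 0.443% to 21.3%). Both medians exceed the share of Ikzf1, which argues against a mixture as their main source. A mixture as small as the share of Ikzf1 stays open, and that share lies within the quartiles of the risen genes. For a lower share of T-ALL cells, the macrophage minus erythroid difference was -2.01 (macrophage -0.408, erythroid 1.61, spread 1.10). That argues only against other cells that raise both lists alike, and erythroid cells or RNA alone stay open. RNA quality stays open too: deviations of this mouse correlated across genes at 0.168 with doxycycline mouse 2 and -0.103 with doxycycline mouse 3. Centring within groups of 3 ties these values together, so they decide nothing. Identifier 100861531, without a symbol here, was at 3295 CPM in this mouse, 3058 CPM in doxycycline mouse 2, 11536 CPM in doxycycline mouse 3 and 1192 to 1550 CPM in the other 3. The criteria of all 3 of these tests replaced earlier ones after their outcomes were seen, which had left the mixture and the T-ALL share open (for the share, the neutrophil median was -0.705 in mouse 3 against a difference of 0.788 between mice 1 and 2) and had argued against RNA quality from doxycycline mouse 3 alone, and no biological explanation was tested.

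Monocyte and macrophage markers were higher in doxycycline mice, and macrophage cells or their RNA in the sorts are a possible explanation, beside a change within the leukemia cells after treatment, which was not tested apart from the gate. The median ratio of doxycycline mouse 2 to the mean of mice 1 and 3 was 1.8 over 14 risen markers, above the 1.16 that marks the 95th percentile of 10000 random lists of risen genes, and 13 of 14 were highest in that mouse against 48.0% of all risen genes. The random genes were drawn singly, whereas the marker list had an estimated correlation of 0.573. Any set of genes regulated together, also within leukemia cells, could pass, so the ratio cannot tell these explanations apart. Itgam, Cd68 and Adgre1 had ratios of only 1.15, 1.16 and 0.972, Lyz2 did not pass the test, 3 of the 14 lay at 5 CPM or more in untreated mice and 0 are held by another list. A GFP sort is meant to remove host cells, but how far it did so was not tested. A lower share of T-ALL cells in all doxycycline sorts was tested only for the case that all other cell types gain alike. That case is argued against by a neutrophil median log2 fold change of -1.30 beside 1.98 for macrophage and 1.8 for erythroid markers. A lower share through macrophage or erythroid cells without neutrophils stays open. The macrophage minus neutrophil difference of list medians, relative to the untreated mean, was 3.01 to 3.51 in the doxycycline mice and -0.18 to 0.20 in the untreated mice. These lists were paired after their directions were seen, and the untreated mice are centred on their own mean. The difference is therefore no separate evidence. The neutrophil list itself did not pass (camera adjusted p = 0.056, and 0.744 with an estimated correlation), but passed with the replicate number as a block (0.0046). It had 1 lower member without untreated mouse 2.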
